A study of Mus musculus with 4 samples.

How the data were processed

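The data were single-cell RNA profiles of CD45+ immune cells from mouse liver in 4 libraries. Per the labels' protocols, each library pooled cells from 5 mice, 1 week after tamoxifen, and the groups were wild type (WT, 2 libraries), a heterozygous hepatocyte deletion of URI (1 library) and a heterozygous hepatocyte deletion of glutamine synthetase, GS (1 library). Livers were digested with collagenase, red cells were lysed, mononuclear cells were taken from a Percoll gradient, and CD45+ cells were sorted, fixed and hybridised to a transcriptome-wide probe set before the libraries were multiplexed. Probe hybridisation measures only genes with a probe, and it reports which probe was ligated, not the sequence of the transcript. The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, without normalisation. Per the submitters' processing notes they were made with Cell Ranger 8.0.0 against mm10. They list 267215 to 401184 barcodes per library, most of them empty droplets.

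Of 32344 listed genes, 15785 had a UMI. Deprecated probes had 59 entries with 0.0649% of UMIs, and 78 symbols were listed more than once. A barcode was kept as a cell with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs. Scrublet, run per library through scanpy at its automatic threshold, removed 5.03% to 5.65% of those cells as doublets. Free RNA was measured from barcodes under 100 UMIs. Cells of all libraries were clustered together without batch integration (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0, seed 1). Clusters took a name only from fixed markers of liver cell types. A name means that the cells resemble that type by those markers (CD4 T-like, B-like and so on), and clusters that failed the naming limits stayed unnamed. Tools were python 3.11.15, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

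Cells are not replicates, so UMIs were summed per library and cell class and the sums were tested with edgeR's quasi-likelihood test (TMM scaling, filterByExpr, Benjamini-Hochberg adjustment within each class at 0.05). A class was tested with at least 50 cells in each library. All 4 libraries entered each fit. The spread came from the 2 WT libraries alone, which leaves 1 residual degree of freedom, and each single knockout library was assumed to vary like WT. Every p-value therefore rests on the difference between 2 WT libraries. The labels give each library its own pool but do not say how the mice were assigned, so this spread may be partly technical. Cell class shares were tested with the same edgeR test on cell counts, with exact Clopper-Pearson 95% intervals beside them. Intervals and floors of 3 counts cover counting error only. No permutation of the libraries was used, because 1 library against 2 cannot reach the threshold.

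Lists of 28 gene groups were tested with camera (preset correlation 0.01, again with an estimated correlation) and with fry. They covered type I interferon and interferon gamma responses, MHC class I and class II presentation, NF-kB inflammatory response, chemokines and chemokine receptors, cytotoxic effectors, T cell activation and exhaustion, naive and memory T cells, B cell activation and antibody secretion, complement and efferocytosis, alternative macrophage activation, lipid-associated macrophages, growth factors of liver regeneration, Wnt ligands, G2M and S phase, glycolysis, the TCA cycle, oxidative phosphorylation, cholesterol synthesis, glutamine and glutamate handling, ATF4 amino acid stress, HIF1A targets, p53 targets, iron and heme handling, dissociation and immediate early response, and hepatocyte transcripts. Genes were named by a fixed rule: in the Kupffer and monocyte classes and the 3 largest other tested classes, the 3 largest rises and 3 largest falls per contrast that passed the threshold, with a mean of at least 20 CPM (UMIs scaled to a common library total) and a knockout level outside both WT values. For a list, up to 4 members with the smallest adjusted p were eligible. The rule was met by Eif2s3y and Ddx3y only, and other genes named below were chosen after their values were seen, as a few calls or as examples. Cell limits, markers, lists, tests, this rule and the alternatives, except those named next, were chosen before the data were examined. The sum of all kept cells per library, fry as an alternative, counts against each WT library alone, and thinning of cells for the granule genes were chosen after seeing the data, as were the counts of genes over 2-fold apart between libraries.

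Genes over 2-fold apart between library pairs were counted in sums thinned to equal UMIs, among genes of at least 20 CPM with a pseudocount of 2 CPM, beside 20 draws of sampling noise. The overlap of the knockouts was set beside 100 simulations of unchanged groups against shared WT libraries, all drawn with the common spread of the class. The tests were checked on simulated counts with 200 genes changed by known folds, in 5 draws for each of 5 classes and the sum of all kept cells. The simulated classes were monocytes, B cells, CD8 T cells, CD4 T cells and neutrophils. Alternatives were other cell limits, doublets kept, Leiden resolution 2.0, DESeq2 size factors, DESeq2's Wald test, no filter on low counts, only the compared libraries in the fit, subtraction of free RNA, equal cell numbers, shares of named cells, and each WT library left out. Without a WT library, fold changes were refitted by edgeR with the offsets and dispersions of the fit of all 4 libraries. Gene positions are whole genes, introns included, from the GENCODE vM21 annotation of mm10.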

Results

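The series profiled CD45+ cells of mouse liver after heterozygous deletion of URI, a prefoldin-family chaperone, or of glutamine synthetase (GS, encoded by Glul), in hepatocytes. The 4 libraries were 1 GS, 1 URI and 2 WT libraries, each from 5 pooled mice. They held 39451266 UMIs (GS), 51920505 (URI), 37783065 (WT replicate 1) and 24041049 (WT replicate 2). After filters 7451, 8587, 8002 and 7038 cells were left in that order, with medians of 4376, 4881, 3719 and 2616 UMIs and 2316, 2474, 2065 and 1514 genes per cell. Before doublets were removed, cells held 93.9% to 95.6% of each library's UMIs. The URI and GS groups had no replicate, so no spread within them was measured.

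The targeted genes came first. Uri1 (ENSMUSG00000030421, chromosome 7, 37959992 to 38023551) was at 93.4 CPM in the URI library, 91.8 and 84.0 in the WT libraries and 88.7 in the GS library, a log2 change of 0.09 (SE 0.42) for URI against WT. Glul (ENSMUSG00000026473, chromosome 1, 153899944 to 153909723) was at 72.3 CPM in the GS library, 70.0 and 87.6 in the WT libraries and 79.5 in the URI library, a log2 change of -0.12 (SE 0.42) for GS against WT, and 0.05 without WT replicate 2. Both had an adjusted p of 1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Their deletion lies in hepatocytes, outside the sorted cells, so these levels do not check the labels.

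The 26 clusters gave 13 named classes of lymphoid and myeloid cells. B cells made up 15.8% of cells in the GS library, 21.7% in the URI library and 20.8% and 26.9% in the WT libraries, and CD8 T cells 16.4%, 13.4%, 18.7% and 10.2%. CD4 T cells were at 10.8%, 11.2%, 9.76% and 8.37%, and NK cells at 8.43%, 8.47%, 10.8% and 9.36%. NKT cells took 9.43%, 8.76%, 4.47% and 7.81%, and neutrophils 8.52%, 7.87%, 9.01% and 15.2%. Monocytes took 1.52%, 2.53%, 1.79% and 3.15%, regulatory T cells 4.24%, 4.10%, 3.97% and 3.40%, and dendritic cells 0.564%, 0.489%, 0.350% and 0.966%. At Leiden resolution 2.0 the regulatory T cell class held 1.13%, 1.83%, 1.92% and 1.07%, so most of its cells lost that name, and CD4 T cells held 13.2%, 13.04%, 11.2% and 9.65%. Basophils took 0.604%, 0.908%, 0.787% and 0.611%. An unnamed lymphoid group, cluster 7 (leading genes Trdc, Klra6, Gpr15 and Ikzf2), held 4.52%, 2.88%, 6.50% and 2.10%. Kupffer cells formed no class: at least 2 of 5 Kupffer markers were found in 1 cell of the URI library and in 0 cells of the GS, WT replicate 1 and WT replicate 2 libraries, which allows up to 0.0403%, 0.0375% and 0.0426%. This limits cells in which those markers are detected, not the share of Kupffer cells. The gradient and the CD45 sort, and the lower depth of WT replicate 2, can set such shares.

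**Figure D1:**
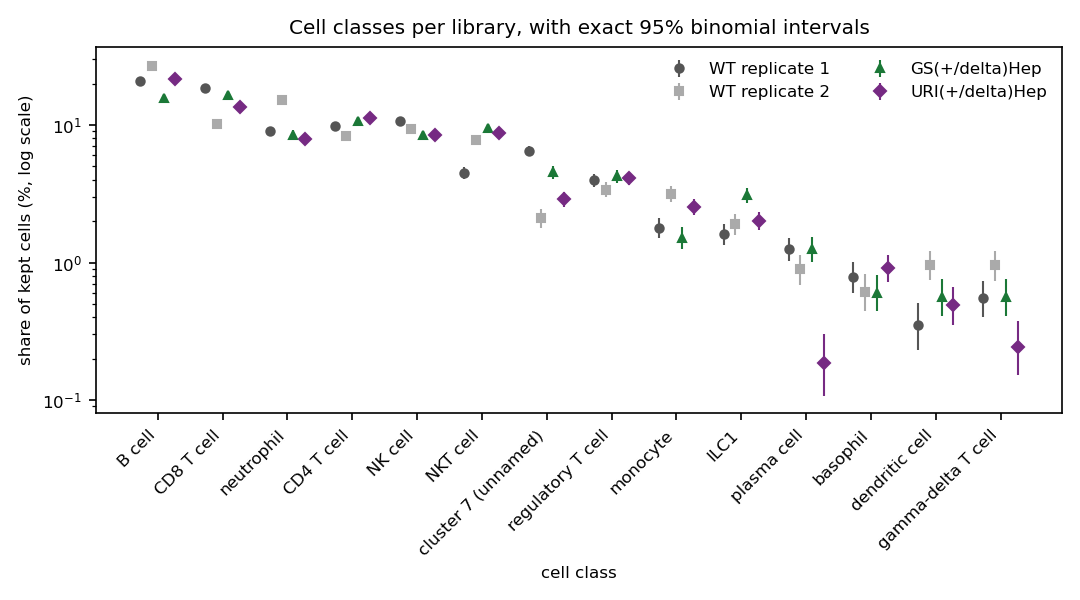
Share of kept cells (percent, log axis) in each named cell class per library, with exact 95% intervals. Plasma cells lie lowest in the URI library, at 0.186% against 1.25% and 0.895% in the WT libraries.

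No class share differed from WT by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15 classes. Plasma cells, which secrete antibody, were at 0.186% of the URI library (16 cells, exact 95% interval 0.107% to 0.302%) and a mean of 1.07% in WT, a log2 ratio of -2.52 (SE 0.79, adjusted p = 0.0922). Plasma cells had a median of 18243 UMIs in the URI library, 903 in the GS library and 2118.5 and 670 in the WT libraries, so the share depends on barcodes of few UMIs. At a limit of 1000 UMIs it was 0.204% (URI), 0.564% (GS), 1.23% and 0.251% (WT), a log2 ratio to WT of -1.86 (adjusted p = 0.580), and with a limit per library -1.69 (adjusted p = 0.744). Gamma-delta T cells were at 0.245% in the URI library and a mean of 0.751% in WT (log2 -1.61, SE 0.75, adjusted p = 0.373), and at Leiden resolution 2.0 at 0.641% and 1.60%. In the GS library, ILC1, tissue-resident innate lymphoid cells, were at 3.07% against a mean of 1.76% in WT (log2 0.81, SE 0.63, adjusted p = 0.829). Plasma cells also lay below the GS library (1.25%), with a log2 ratio of URI to GS of -2.73 (SE 0.85, adjusted p = 0.0886), which was -1.46 at 1000 UMIs and -0.83 with a limit per library. In simulated cell counts the test recovered 31 of 50 shares changed 8-fold (62%), so smaller changes in rare classes could not be excluded.

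The 2 WT libraries differed from each other in expression more than any other library pair did in 10 of 10 tested classes. In CD8 T cells 567 genes were over 2-fold apart between the WT libraries at equal UMIs, against 12 between GS and URI and at most 0 from sampling noise. The same counts were 427 and 22 in CD4 T cells, 384 and 17 in B cells, 572 and 27 in NK cells, 389 and 74 in monocytes and 362 and 167 in neutrophils. WT replicate 2 stood apart from the other libraries in all kept cells, with 312 genes over 2-fold from GS, 167 from URI and 576 from WT replicate 1, against 22 to 61 among those 3. The GS library differed from WT replicate 2 in more genes than from WT replicate 1 in 10 of 10 classes (290 against 50 in CD8 T cells). The URI library did in 8 of 10 classes, but not in NK cells (93 against 112) or cluster 7 (327 against 471), and in CD8 T cells the counts were 89 and 88. The immediate early genes, which cells induce within minutes of stress, had a median log2 difference of 0.90 (WT replicate 2 minus WT replicate 1) in all kept cells, with 23 of 25 members higher, and of 1.43 in NK cells. The summed level of this list in free RNA was 35567 CPM in WT replicate 2 and 17627 in WT replicate 1. The knockout libraries lay between the WT libraries for 93.9% (URI) and 91.0% (GS) of the genes over 2-fold apart in all kept cells, which were chosen for a wide WT gap, and for 65.4% and 59.5% of all genes compared. WT B cells came mainly from cluster 2 in WT replicate 2 (94.9%) and from cluster 3 in WT replicate 1 (74.1%), so values within B cells compare different clusters. This WT difference enters the error of every comparison with WT.

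**Figure D2:**
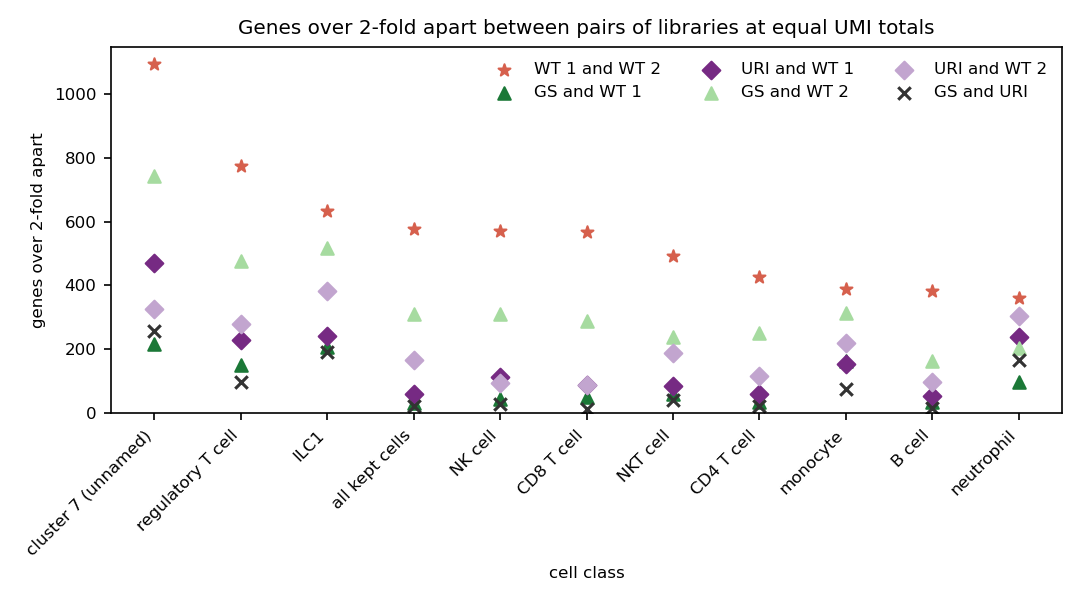
Number of genes over 2-fold apart at equal UMIs for each pair of libraries, per tested cell class. The WT pair has the highest count in all 10 classes, for example 567 in CD8 T cells.

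The first comparison asked what the loss of 1 Glul copy in hepatocytes changed in liver immune cells. In the GS library, ILC1 had lower Igfbp4 (ENSMUSG00000017493, chromosome 11, 99041244 to 99054392), an insulin-like growth factor binding protein, at 7.27 CPM against 97.4 and 91.0 in WT (log2 -3.67, SE 0.54, adjusted p = 0.00408). ILC1 also had lower Ccr7 (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077), a lymph-node homing receptor, at 7.27 CPM against 103 and 72.0 (log2 -3.57, SE 0.55, adjusted p = 0.00477). The Igfbp4 UMIs came from 4 GS cells and from 13 and 9 WT cells, and both genes are also expressed by naive T cells. The Y-linked Eif2s3y (ENSMUSG00000069049, chromosome Y, 1010543 to 1028847), a translation initiation factor subunit, was higher in cluster 7 (122 CPM against 1.56 and 37.6, log2 3.15, SE 0.57, adjusted p = 0.000356). That log2 change was 1.69 without WT replicate 1 and 6.23 without WT replicate 2, and its call held in 8 of 9 alternatives (adjusted p 0.000341 to 1.00). The labels give no sex of the pooled mice. Summed Y-linked genes in all kept cells were at 9.95 and 173 CPM in the WT libraries, which share a genotype, and at 170 in the GS library. In cluster 7 they were at 9.01 and 204 CPM in WT and 366 in the GS library. Y-linked level thus differed between pools without a deletion, so this call is no evidence of an effect of the GS deletion. Igfbp4 and Ccr7 each held in 5 of 8 alternatives (adjusted p up to 0.999). They were lost by DESeq2, at Leiden resolution 2.0 and with doublets kept, where their log2 changes were -1.47 and -1.49. These 3 genes were the calls of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 10 classes, where DESeq2 called 0. The other 8 classes had 0 calls by edgeR, with 19 (CD4 T cells), 15 (B cells), 32 (NK cells), 61 (neutrophils), 42 (CD8 T cells), 29 (NKT cells), 253 (monocytes) and 66 (regulatory T cells) genes at an unadjusted p under 0.05, and 0 by DESeq2.

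MHC class II presentation genes, which display peptides to CD4 T cells, fell as a list in 9 of the 10 classes of the GS library, with medians from -1.38 (ILC1) to -0.30 (monocytes) on the log2 scale (adjusted p = 0.958 with an estimated correlation). In the regulatory T cell class 12 of 12 members lay below both WT libraries (median -0.80), where summed B cell markers were at 467 CPM in the GS library and 1127 and 697 in WT. Cluster 23 held 6.65% of this class in the GS library and 18.9% and 11.3% in WT, so the mix of clusters differed. Of the 316 GS, 318 WT replicate 1 and 239 WT replicate 2 cells of this class, most lost the name at Leiden resolution 2.0. There the clusters led by Foxp3 held 63 and 21 GS cells, 91 and 63 of WT replicate 1 and 48 and 27 of WT replicate 2. In neutrophils 9 of 12 members lay below both (median -0.85), beside B cell markers at 57.7 CPM against 191 and 62.3. In CD8 T cells 6 of 12 did (median -0.62), beside B cell markers at 53.8 CPM against 57.7 and 100.4. In ILC1 4 of 12 did, and the summed list was at 363 CPM in the GS library, between the WT libraries at 293 and 1341, with B cell markers at 34.6 against 48.7 and 255. In cluster 7 these markers were at 40.2 CPM against 48.99 and 140, in NK cells at 22.2 against 29.3 and 56.5, and in NKT cells at 29.4 against 35.5 and 67.4. Adjusted over the list alone, 2 members were lower in CD8 T cells, 3 in cluster 7 and 1 in ILC1, while 0 were over all genes by edgeR. In CD8 T cells Cd74, the invariant chain, was at 78.8 CPM in the GS library and at 59.4 and 387 in WT (log2 -1.49, SE 0.47). CD4 T cells had 3 of 12 members below both WT libraries, beside B cell markers at 40.8 CPM against 39.4 and 94.8, and the list's WT replicate 2 minus WT replicate 1 median was 1.06. Free RNA held Cd74 at 3433 CPM in the GS library and 3707 and 5547 in the WT libraries.

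Type I interferon response genes, the antiviral transcripts, fell as a list in 6 classes of the GS library (adjusted p = 0.958 with an estimated correlation). The medians were -0.63 in NKT cells (21 of 25 members below both WT libraries), -0.61 in neutrophils (20 of 25), -0.54 in ILC1 (18 of 23), -0.49 in monocytes (16 of 25), -0.29 in CD4 T cells and -0.28 in B cells (12 of 25 each). In neutrophils Ifit3 was at 43.1 CPM in the GS library against 222 and 107 (log2 -1.93, SE 0.58), which did not pass edgeR over all genes. No member passed adjusted over the list alone. Neutrophil cluster 17 held 9.85% of the class in WT replicate 1, 0% in WT replicate 2 and 0.630% in the GS library, so the mix of clusters differed.

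Cytotoxic effector genes rose as a list in CD8 T cells of the GS library (median log2 0.50, 16 of 20 members above both WT libraries; adjusted p = 0.958 with an estimated correlation). Their summed level was 9727 CPM against 7007 and 6244 in WT and 7410 in the URI library, and 4 members were higher adjusted over the list alone. Klrg1, a receptor of effector cells, was at 55.9 CPM against 14.4 and 6.87 (log2 2.34, SE 0.53), and Gzmk, a granzyme, at 73.4 against 32.7 and 16.97 (log2 1.53, SE 0.46). Fasl and Zeb2, a death ligand and an effector transcription factor, also lay over 2-fold above both WT libraries, by log2 1.47 and 1.34 for Fasl and by 1.85 and 1.59 for Zeb2. With Klrg1 and Gzmk they were the 4 CD8 T cell genes of at least 20 CPM that lay over 2-fold beyond both WT libraries in the GS library. CD8 T cells came from clusters 6 and 9, and cluster 9 held 33.7% of them in the GS library and 27.4% and 17.02% in WT. At Leiden resolution 2.0 a cluster led by Gzmk, Ccl5 and Klrg1, with Cd8a among its leading genes, held 219 GS and 108 URI cells. It held 125 cells of WT replicate 1 and 54 of WT replicate 2. The rise of the list was not separated from this difference in cell mix.

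In monocytes of the GS library, 4 lists rose: cytotoxic effectors (median log2 1.19, 12 of 15 members above both WT libraries), chemokines and chemokine receptors (0.59, 14 of 23), NF-kB inflammatory response (0.47, 17 of 27) and T cell activation and exhaustion (0.59, 8 of 14); adjusted p = 0.958 with an estimated correlation. The chemokine Ccl4 was at 454 CPM against 120 and 178 (log2 1.60, SE 0.37) and Ifng, a lymphocyte cytokine, had a log2 change of 2.58 (SE 0.53). The summed cytotoxic list was at 2974 CPM, between the WT libraries at 2015 and 3193, and the summed T cell activation list at 4210 CPM, below 4228 and 6731. Adjusted over the list alone, 3 cytotoxic genes were higher, 3 chemokine genes were higher and 1 lower, and 1 NF-kB gene was higher. Summed B cell markers in this class were at 157 CPM against 556 and 350, and hepatocyte transcripts at 417 against 233 and 285.

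Other lists called in the GS library moved in fewer classes (adjusted p = 0.958 with an estimated correlation). Alternative macrophage activation fell in CD8 T cells, ILC1, NK cells, NKT cells and cluster 7 (medians -0.61 to -0.48), and complement and efferocytosis in CD4 T cells (-0.83), CD8 T cells (-0.62) and monocytes (-0.30). S phase genes rose in NKT cells (0.21) and regulatory T cells (0.22) and fell in neutrophils (-0.95). G2M genes rose in CD4 T cells (0.38) and fell in NK cells (median -0.17, mean -0.82). Interferon gamma response genes rose in monocytes (0.24) and regulatory T cells (0.21) and fell in neutrophils (-0.38). NF-kB genes fell in CD4 T cells (-0.41), naive and memory T cell genes in ILC1 (-0.40) and B cells (-0.18), cholesterol synthesis in ILC1 (-0.34), and B cell activation in regulatory T cells (-0.25). Chemokine genes in ILC1 passed camera as lower, but their median was 0.00, their mean -0.50 and their summed level 19090 CPM, above 18138 and 17781 in WT. Growth factors in regulatory T cells passed as higher with a median of -0.08, a mean of 0.33 and a sum of 681 CPM between 403 and 833, where 1 member was higher adjusted over the list alone. In all kept cells, lipid-associated macrophage genes fell (-0.20), and hepatocyte transcripts fell (median -1.84, 11 of 14 members below both WT libraries, with Alb at 1.51 CPM against 16.5 and 4.99). The summed hepatocyte list was at 41.8 CPM against 60.7 and 74.1, and in free RNA at 82.6 against 143 and 88.1. Cluster 21, led by Alb, held 6 GS cells and 10 and 475 WT cells. The fall was not separated from free RNA or from that cluster. Over 258 tests of 26 lists in the 10 classes camera called 43. The summed level, which abundant members dominate, lay beyond both WT libraries on the called side for 27 of them, between them for 14 and on the other side for 2. Those between included alternative macrophage activation in all 5 of its classes, type I interferon in CD4 T cells and B cells, S phase in NKT cells and regulatory T cells, NF-kB in CD4 T cells and naive and memory T cell genes in B cells. With an estimated correlation 0 were called (lowest adjusted p = 0.958), and 0 by fry (lowest adjusted p = 0.998). Here and in the other contrasts both tests rest on 1 residual degree of freedom, and their power was not simulated. Their 0 calls do not show that no list changed.

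In the sum of all kept cells, a summary chosen after seeing the data, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3 genes for GS against WT. Cpne4 (ENSMUSG00000032564, chromosome 9, 104547286 to 105034544), a copine, had 319 UMIs in 242 GS cells against 7 and 4 UMIs in WT (ratio 45.3, 95% counting interval 24.99 to 91.7; adjusted p = 0.0167). Its fitted log2 change was 5.44. Igkv4-91 (chromosome 6, 68768555 to 68769103), an immunoglobulin light chain segment, was lower (log2 -6.09, adjusted p = 0.0448), but 1988 of its 2034 UMIs in WT replicate 2 came from 1 cell, and its log2 change was -2.90 without that library and -7.01 without WT replicate 1. Ighg1 (chromosome 12, 113325240 to 113330523), an IgG heavy chain constant gene, was lower (log2 -3.57, adjusted p = 0.0167). Its 180 UMIs in WT replicate 1 came from 5 cells and 56 of 109 in WT replicate 2 from 1 cell, and its UMI ratio of 0.0865 was 0.135 without the top cell of each library. All 3 calls were lost with DESeq2 size factors, with only the compared libraries, at 1000 UMIs, with a limit per library and with doublets kept (0 calls each by edgeR, with 77, 68, 74, 52 and 72 genes at an unadjusted p under 0.05), and DESeq2 called 2. Over the alternatives the adjusted p reached 0.749 for Cpne4 and Ighg1 and 1.00 for Igkv4-91. Immunoglobulin and T cell receptor segments are similar in sequence, so counts of single segments are uncertain.

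For GS against WT on simulated counts, edgeR recovered 0% to 8.96% of 2-fold, 0% to 61.2% of 4-fold and 0% to 88.8% of 8-fold changes over 5 classes and all kept cells, lowest in neutrophils at 0%. False calls made up 4.17% to 20.6% of calls where 5% was nominal. ILC1 and cluster 7, which held the calls within classes, were not simulated.

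**Figure D3:**
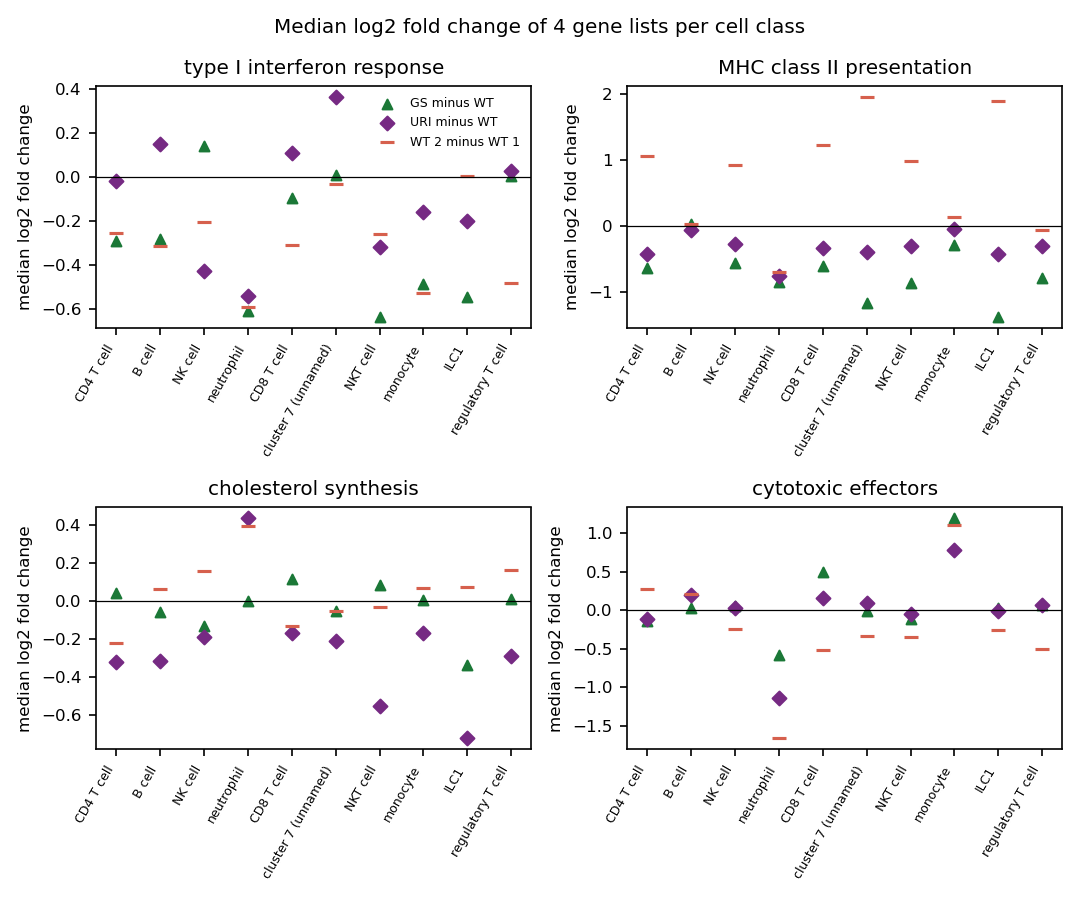
Median log2 fold change of 4 fixed gene lists (type I interferon, MHC class II, cholesterol synthesis, cytotoxic effectors) in each class for GS and URI against WT, with the WT replicate 2 minus WT replicate 1 median beside them. In regulatory T cells MHC class II lies at -0.80 for GS, while the WT libraries differ by -0.07. Most cells of this class lost that name at Leiden resolution 2.0. B cell markers in that class were also lower in the GS library than in both WT libraries. In ILC1 the WT libraries differed widely, with the summed MHC class II list at 293 and 1341 CPM.

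The second comparison asked what the loss of 1 Uri1 copy in hepatocytes changed in the same cells. In monocytes of the URI library, the Y-linked Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629), an RNA helicase, was at 113 CPM against 4.88 and 8.28 in WT and 16.2 in the GS library (log2 4.08, SE 0.43, adjusted p = 0.00356). Eif2s3y in monocytes had 122 UMIs against 2 and 1 in WT (ratio 53.8, 95% counting interval 17.99 to 265; adjusted p = 0.00356). CD8 T cells also had higher Eif2s3y, at 145 CPM against 2.79 and 60.2 (log2 2.28, SE 0.43, adjusted p = 0.00127), a log2 change of 1.27 without WT replicate 1 and 5.69 without WT replicate 2. In cluster 7 Eif2s3y was higher too (log2 3.32, SE 0.57, adjusted p = 5.98e-05), at 1.87 without WT replicate 1 and 6.41 without WT replicate 2, and the call held in 8 of 9 alternatives (adjusted p up to 1.00). Both genes have relatives on chromosome X, and the labels give no sex of the pooled mice. Summed Y-linked genes in all kept cells were at 428 CPM in the URI library, 170 in the GS library and 9.95 and 173 in WT. The pools thus differed in Y-linked level, and so did the WT pools, which share a genotype. Calls of Y-linked genes are therefore no evidence of an effect of the URI deletion. For other genes, the sex makeup of the pools cannot be told apart from genotype in the comparisons with WT.

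Cluster 7 of the URI library had higher Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), an interferon-induced chemokine, at 161 CPM against 9.37 and 63.9 in WT (log2 2.37, SE 0.53, adjusted p = 0.0246), 1.33 without WT replicate 1 and 4.10 without WT replicate 2. Over alternatives with a test the log2 change of Cxcl10 ranged from 0.98 to 2.43. Nrn1 (chromosome 13, 36725361 to 36735131), neuritin, passed there with 63 UMIs against 0 and 1, but all 63 came from 1 cell (log2 6.40, 4.22 without WT replicate 1 and 9.24 without WT replicate 2). Trbv14 (chromosome 6, 41135145 to 41135616), a T cell receptor segment, was lower (log2 -2.72, SE 0.64, adjusted p = 0.0460), with 20 UMIs from 1 URI cell against 14 and 4 WT cells with the segment. Over the 10 classes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment made 7 calls of 5 genes, with Eif2s3y called in 3 classes, and DESeq2 made 18 calls, 16 of them in neutrophils. In the 7 classes with 0 calls by edgeR, 13 (CD4 T cells), 13 (B cells), 16 (NK cells), 266 (neutrophils), 26 (NKT cells), 87 (ILC1) and 40 (regulatory T cells) genes had an unadjusted p under 0.05, and DESeq2 called 0 there outside neutrophils. The CD8 T cell call of Eif2s3y held in 2 of 9 alternatives (adjusted p 0.00253 to 1.00), Cxcl10 in 7 of 9, Trbv14 in 6 of 9, Nrn1 in 6 of 8 and both monocyte calls in 7 of 8, each with an adjusted p of up to 1.00.

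Secondary granule genes, made by maturing neutrophils, stood out in the URI library. In all kept cells Camp (ENSMUSG00000038357, chromosome 9, 109847379 to 109849617) was at 555 CPM against 114 and 96.2 in WT (log2 2.40, SE 0.43, adjusted p = 0.0179). Ngp (ENSMUSG00000032484, chromosome 9, 110419747 to 110423012) rose by log2 2.73 (SE 0.47, adjusted p = 0.0158) and Ltf (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767), lactoferrin, by 2.79 (SE 0.43, adjusted p = 0.00499), all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Camp and Ngp lost the call with DESeq2 size factors, at 1000 UMIs and with a limit per library (adjusted p up to 0.629), and Ltf with a limit per library (0.431). Cells with at least 3 of 4 granule genes (Camp, Ngp, Ltf and Lcn2) made up 3.81% of the URI library (327 cells, exact 95% interval 3.41% to 4.23%), 0.812% and 0.568% of the WT libraries and 0.309% of the GS library. Among B and T cells, which should lack these genes, the share was 0.377% in the URI library (median 4968 UMIs, against 4881 over all its cells) and at most 0.0313% in the others. After thinning to 1000 UMIs, which left out 741 (URI), 689 and 665 (WT) and 712 (GS) shallower cells, the shares were 2.55%, 0.506%, 0.408% and 0.148%. In the neutrophil class 81 genes lay over 2-fold beyond both WT libraries in the URI library, 74 of them higher, among them Chil3 (log2 3.01 and 4.31 from each WT library), Cybb (2.05 and 3.34) and Ly6g (1.18 and 1.74). Neutrophil cluster 24, led by granule genes, held 17.01% of URI neutrophils and 1.66% and 1.96% of WT neutrophils. Free RNA of the URI library held these genes at 4122 CPM, against 731 and 833 in WT.

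**Figure D4:**
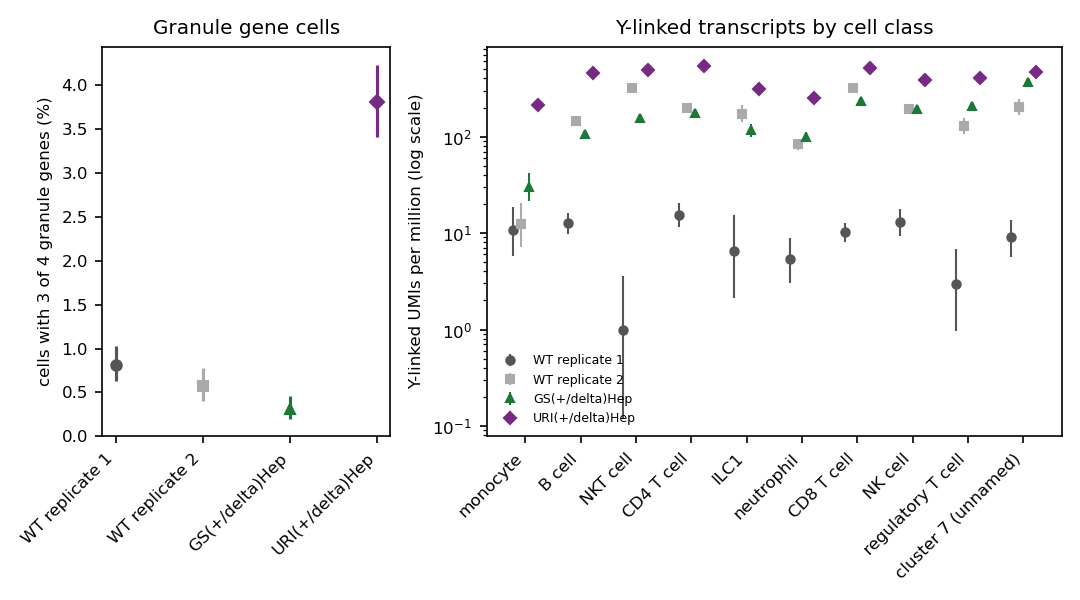
Percent of kept cells with at least 3 of 4 granule genes per library, with exact 95% intervals, and summed Y-linked CPM per cell class and library on a log axis. The URI library has 3.81% granule gene cells, and GS monocytes have 30.2 Y-linked CPM against 213 in URI monocytes.

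Immunoglobulin genes in the sum of all kept cells rested on single cells. Ighg1 was higher in the URI library (log2 6.30, adjusted p = 3.02e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 19224 of its 19453 UMIs came from 1 cell. The UMI ratio to WT of 80.5 was 1.69 without the top cell of each library. Ighg2b (chromosome 12, 113302965 to 113307933) was lower (log2 -5.20, adjusted p = 0.00499), with 4564 of 4725 UMIs of WT replicate 2 in 1 cell. Its log2 change was -3.38 without that library and -5.98 without WT replicate 1, and its call held in 3 of 6 alternatives (adjusted p up to 1.00).

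Cholesterol synthesis genes fell as a list in 7 classes of the URI library (adjusted p = 0.994 with an estimated correlation). The medians were -0.72 in ILC1 (14 of 20 members below both WT libraries), -0.55 in NKT cells (15), -0.32 in CD4 T cells (13), -0.32 in B cells (14), -0.29 in regulatory T cells (9), -0.17 in CD8 T cells (9) and -0.17 in monocytes (10). Stard4, a sterol carrier, had a log2 change of -0.84 in CD4 T cells, which did not pass over all genes by edgeR.

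URI neutrophils showed lower inflammatory and interferon lists beside the granule genes (adjusted p = 0.994 with an estimated correlation). Type I interferon genes fell (median -0.54, 18 of 25 members below both WT libraries), as did interferon gamma (-0.52, 13 of 22), NF-kB (-0.59, 10 of 27), immediate early (-0.56, 17 of 25) and chemokine genes (-0.59, 10 of 20). Cytotoxic (-1.14), MHC class II (-0.77, beside B cell markers at 66.4 CPM against 191 and 62.3), B cell activation (-0.45), ATF4 amino acid stress (-0.60) and naive T cell genes (-0.60) fell too. Oxidative phosphorylation genes rose (0.28, 21 of 29 above both WT libraries; summed 1248 CPM against 1106 and 1011). Cxcl10 in neutrophils was at 6.21 CPM against 37.6 and 37.1 (log2 -2.58, SE 0.40) and was the 1 interferon gamma member lower adjusted over the list alone. WT replicate 1 neutrophils included cluster 17, at 9.85% of them. At equal UMIs the NF-kB list had a median log2 difference of 0.01 from WT replicate 1 and -0.73 from WT replicate 2, so its fall was against WT replicate 2. At Leiden resolution 2.0 a neutrophil cluster led by G0s2, Cd14 and Tgm2 held 235 cells of WT replicate 2. It held 2 cells of WT replicate 1, 4 URI cells and 1 GS cell.

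URI monocytes had higher G2M genes as a list (summed 163 CPM against 39.1 and 46.8 in WT and 31.03 in the GS library; adjusted p = 0.994 with an estimated correlation). Of its 7 members 6 lay above both WT libraries and 4 were higher adjusted over the list alone. The mitotic cyclin Ccnb2 was at 21.6 CPM against 0.814 and 3.31, and Ccna2 at 17.9 CPM against 0 UMIs in both WT libraries. NF-kB (0.54, 15 of 27 above both WT libraries), cytotoxic (0.78, 10 of 15) and chemokine genes (0.36, 11 of 23) rose as lists, with Tnfaip3, an NF-kB inhibitor, at log2 1.57 (SE 0.41). Genes of T and NK cells moved with them, such as Ifng (log2 2.34) and Ctsw (1.44). Naive and memory T cell genes passed camera as higher (median 0.24), but their summed level was 3538 CPM, below 3828 and 4526 in WT.

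Type I interferon genes went both ways in other URI classes (adjusted p = 0.994 with an estimated correlation). They rose in cluster 7 (median 0.36, 18 of 25 above both WT libraries), B cells (0.15) and CD8 T cells (0.11) and fell in NK cells (-0.42, 16 of 24 below both) and NKT cells (-0.31, 15 of 25). MHC class II genes fell in CD4 T cells (-0.44), CD8 T cells (-0.34), cluster 7 (-0.40) and regulatory T cells (-0.31). Their summed level lay between the WT libraries in CD4 T cells (633 CPM against 561 and 1116), CD8 T cells (619 against 567 and 1030) and cluster 7 (438 against 367 and 1077). B cell markers there were at 57.7 CPM against 39.4 and 94.8, 65.7 against 57.7 and 100.4, and 57.5 against 48.99 and 140, and in regulatory T cells at 705 against 1127 and 697. T cell activation genes rose in CD8 T cells (0.34), regulatory T cells (0.21) and cluster 7 (0.07), and cytotoxic genes in B cells (0.20) and CD8 T cells (0.15). ATF4 amino acid stress genes fell in NKT cells (-0.42) and B cells (-0.28), and immediate early genes in NKT cells (-0.36) and B cells (-0.22). In cluster 7 NF-kB (0.27) and interferon gamma genes (0.13) rose. Chemokine genes (median 0.01) and immediate early genes (median -0.01, mean 0.10) passed camera there as higher, but their sums lay between the WT libraries, at 12421 CPM against 13485 and 11151 and at 28314 against 12860 and 36509. Naive and memory T cell genes fell in ILC1 (-0.31, 2 members lower adjusted over the list alone), and in all kept cells hepatocyte transcripts fell (-0.61). The summed hepatocyte list was at 44.2 CPM against 60.7 and 74.1 in WT, and in free RNA at 66.0 against 143 and 88.1. This fall was not separated from free RNA. Camera called 48 of 258 list tests, with the summed level on the called side of both WT libraries for 31, between them for 16 and on the other side for 1. Besides those named, sums lay between for T cell activation in all 3 classes, for type I interferon in B and CD8 T cells, for ATF4 stress and immediate early genes in NKT and B cells, for NF-kB in cluster 7 and for alternative macrophage activation in CD8 T cells (median 0.07, called higher). With an estimated correlation 0 were called (lowest adjusted p = 0.994), and 0 by fry (lowest adjusted p = 0.998).

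For URI against WT on simulated counts, edgeR recovered 0% to 7.16% of 2-fold, 0.299% to 67.5% of 4-fold and 3.64% to 92.7% of 8-fold changes, lowest in neutrophils at 3.64%. Neutrophil recovery at 8-fold was 85.8% when all genes were simulated with 1 common spread, so the 0 neutrophil calls depend on how gene spreads vary and do not show that no gene differed. False calls made up 4.86% to 58.1% of calls where 5% was nominal, the highest share in neutrophils (18 of 31 calls), so single calls are weak evidence. Cluster 7, which held some of the calls, was not simulated.

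The third comparison set the URI library against the GS library. The granule genes were higher in the URI library in all kept cells, Camp by log2 3.83 (SE 0.57, adjusted p = 0.00189) and Ngp by 3.99 (SE 0.64, adjusted p = 0.00314), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cpne4 had 0 UMIs in the URI library, at least 139-fold lower than in the GS library against a floor of 3 counts over the library. Each of the 3 held in 5 of 6 alternatives and was lost with a limit per library (adjusted p up to 0.238). Within the 10 classes 1 gene passed, Trbv14 in cluster 7 (log2 -3.47, SE 0.69, adjusted p = 0.00427), from 1 URI cell and 12 GS cells. DESeq2 called 16 over the 10 classes, 15 of them in neutrophils. In the 9 classes with 0 edgeR calls, 10 (CD4 T cells), 22 (B cells), 26 (NK cells), 204 (neutrophils), 21 (CD8 T cells), 26 (NKT cells), 118 (monocytes), 50 (ILC1) and 31 (regulatory T cells) genes had an unadjusted p under 0.05, and DESeq2 called 1 there outside neutrophils, in NKT cells.

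Type I interferon genes were higher as a list in 7 URI classes than in GS, with medians of 0.47 in ILC1, 0.43 in B cells, 0.37 in cluster 7, 0.32 in CD4 T cells, 0.27 in monocytes, 0.20 in CD8 T cells and 0.20 in NKT cells, and lower in NK cells at -0.45 (adjusted p = 0.973 with an estimated correlation). MHC class II genes were higher in 6 classes (medians 0.40 to 0.66), and B cell markers were higher in the same classes. These were at 103.8 CPM in the URI library and 34.6 in the GS library in ILC1, 705 and 467 in regulatory T cells, 57.5 and 40.2 in cluster 7, 65.7 and 53.8 in CD8 T cells, 50.1 and 29.4 in NKT cells and 38.3 and 22.2 in NK cells. Cholesterol synthesis was lower in NKT cells (-0.62), ILC1 (-0.43), monocytes (-0.41), CD4 T cells (-0.32), regulatory T cells (-0.31) and CD8 T cells (-0.29) and higher in neutrophils (0.52). Cytotoxic genes were lower in CD8 T cells (-0.41), where Gzma had a log2 difference of -2.09 (SE 0.53) and 2 members were lower adjusted over the list alone. At Leiden resolution 2.0 the cluster led by Gzmk held 108 URI and 219 GS cells. NF-kB genes were higher in cluster 7 (0.57), regulatory T cells (0.42) and NK cells (0.27), and lipid-associated macrophage genes were higher in B cells (0.27) and lower in CD8 T cells (-0.25). G2M genes were higher in monocytes, with 5 of 7 members higher adjusted over the list alone, and in NK cells (0.70), and lower in CD4 T cells (-0.50). S phase genes were higher in neutrophils (1.05) and lower in regulatory T cells (-0.36) and NKT cells (-0.19). Camera called 51 list tests, with the summed level on the called side for 49 and on the other side for 2, T cell activation in monocytes and chemokines in cluster 7. Of the 51, 0 were called with an estimated correlation (lowest adjusted p = 0.973) and 0 by fry (lowest adjusted p = 1.00).

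The simulated recovery for URI against GS was 0% to 4.48% at 2-fold, 0% to 44.2% at 4-fold and 0% to 77.6% at 8-fold, with 3.92% to 44.7% of calls false. Cluster 7, which held the Trbv14 call, was not simulated. Of the 28 lists, 8 had no camera call where they were tested, which for Wnt ligands was only the sum of all kept cells. Their lowest adjusted p values were 0.0775 for HIF1A targets, 0.0781 for the TCA cycle, 0.0979 for p53 targets, 0.106 for glutamine and glutamate handling, 0.152 for iron and heme handling, 0.173 for MHC class I, 0.181 for glycolysis and 0.582 for Wnt ligands. Camera at the preset correlation was run on simulated counts, in which genes vary independently. It called 30 of 30 changed lists and 0 (GS against WT), 1 (URI against WT) and 1 (URI against GS) of 30 unchanged ones. Each changed list held all genes raised 2-fold to 8-fold, and a call was an unadjusted p under 0.05. This does not show the power for the fixed lists, whose medians were mostly smaller and whose p values were adjusted.

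The fold changes of the knockouts against WT were compared across genes, which are not independent replicates. Their correlation was 0.54 in CD4 T cells, 0.45 in B cells, 0.49 in CD8 T cells and 0.53 in monocytes. Unchanged groups simulated against shared WT libraries, which were simulated too, gave 0.342, 0.333, 0.334 and 0.336. The correlation was below its simulated value in neutrophils (0.296, covariance 0.0416 against a simulated 0.0947) and level with it in cluster 7 (0.345 against 0.345, covariance 0.0301 against 0.121). With GS set against WT replicate 1 and URI against WT replicate 2, the correlation was -0.235 in CD4 T cells, -0.343 in B cells and -0.318 in CD8 T cells, and 0.0497 in monocytes. The reverse pairing gave -0.480, -0.541, -0.624 and -0.0784. With both WT libraries in each comparison, the covariance in these 4 classes was 0.0264, 0.0194, 0.0199 and 0.0596, below the simulated 0.0755, 0.0810, 0.0978 and 0.0653. It lay below the simulated value in every class, so the simulated groups held more shared spread than the data. The simulation therefore cannot tell whether the knockouts shared an effect. Eif2s3y in cluster 7 was the 1 call within the 10 classes shared by both comparisons with WT, which share WT replicate 1, where it was at 1.56 CPM. The WT libraries cannot be split into groups of 2, so part of the correlation may come from the shared controls.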

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

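All tests of explanations in this part were chosen after the results were seen. For the Y-linked genes, the test of free RNA replaced an earlier one that had been computed first and that excluded the same explanation. The test of sex makeup replaced one on genes chosen for their WT difference.

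The first pattern weighed is the expression difference between the 2 WT libraries. Sampling depth was excluded as its cause, since 567 CD8 T cell genes stayed over 2-fold apart at equal UMIs, against 0 in noise draws. The sex makeup of the pools was excluded as the whole cause, because URI and WT replicate 1, with the widest gap in Y-linked level (428 and 9.95 CPM), had 61 genes over 2-fold apart in all kept cells, against 576 between the WT libraries, and GS and WT replicate 2, with levels of 170.3 and 173 CPM, had 312 (at most 0 from noise). A response to cell preparation may contribute, as the immediate early list had its WT difference at the 100th percentile of random lists. The NF-kB inflammatory list stood there too (median log2 difference 0.91, 20 of 23 members higher in WT replicate 2). The random lists were matched on expression, not on how genes vary together, so the percentile does not single out preparation. How many of the genes a response to preparation accounts for was not measured. No other biological explanation was tested, since both libraries carry 1 label.

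The second pattern is the granule gene transcripts of the URI library, where Camp, Ngp and Ltf exceeded the GS library by log2 3.83, 3.99 and 3.84. Free RNA was excluded as their source, because 95.9% of their UMIs in the URI library lay in cells with at least 3 of the 4 genes. Deeper cells were excluded, since 2.55% of cells thinned to 1000 UMIs still held them, against at most 0.697% allowed by the intervals of WT. Cluster 25, led by Camp, Fcnb and Ngp, held 1.11% of the URI library, 0.0125% and 0.0142% of the WT libraries and 0 of 7451 GS cells, which allows up to 0.0403%. An effect of the URI genotype cannot be told apart from this pool of mice or its preparation, because there was 1 URI library.

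The third pattern is the Y-linked level that differs between classes of 1 pool, summed over Ddx3y, Eif2s3y, Kdm5d and Uty. In the GS library it was 14.2% of the URI level in monocytes and 79.3% in cluster 7. Counting error was excluded, since its intervals allow at most 21.6% in monocytes and at least 68.6% in cluster 7. Free RNA was excluded as the source of the cluster 7 level, which is at least 1.95 times that of free RNA. Pools of mice of both sexes that differ in their cell classes could give it, but cannot be tested, because the 5 mice pooled per library have no label of their own.

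Other results differed between the knockouts or stood above WT. Trbv14 in cluster 7 differed between URI and GS by log2 -3.47, from 1 URI cell. Cpne4 differed by a fitted log2 of -11.25, with 0 URI UMIs and so at least 139-fold. Ighg2b differed by log2 -7.31, with 13320 of 21061 GS UMIs in 1 cell. Ighg1 differed by log2 9.86, with 98.8% of URI UMIs in 1 cell and a UMI ratio of 931 that was 12.5 without the top cells. Cluster 1, unnamed and with a median of 861 UMIs, held 12.1% of the GS and 11.4% of the URI library, against 8.14% and 0.966% of WT. Cluster 16, led by Igkv15-103, Trdc and Klre1, held 1.26% of the GS library against 0.112% and 0.0284% of WT.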

How the results depend on the processing

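The sums of all kept cells, fry, each WT library alone for the 2-fold counts and granule gene thinning were chosen after seeing the data. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Without 1 WT library no residual degrees of freedom remain, so those settings give folds and no test. Subtraction of free RNA was not used for monocytes, ILC1, neutrophils or all kept cells, where it took over 50% of UMIs in a library, and gave no sum over classes. Leiden resolution 2.0 leaves the sum of all kept cells as it is and gives no value there. Under alternatives with a test, 126 values of the class share ratios kept their direction and 4 reversed: plasma cells in GS (-0.40 at 1000 UMIs, -0.86 with a limit per library), regulatory T cells in GS (-0.41 at Leiden resolution 2.0) and monocytes in URI (-0.034 at resolution 2.0). No share passed under any of them, and the cause of the reversals was not tested. Without 1 WT library 8 of 52 ratios changed sign, among them CD8 T cells (0.18 in GS, -0.19 without WT replicate 2; -0.11 in URI, 0.40 without WT replicate 1) and dendritic cells (-0.22 in GS, 0.69 without WT replicate 2). Under alternatives with a test the called genes kept their call in 125 values and lost it in 53, in the same direction. The fit of only the compared libraries is not among these values or the counts of alternatives given per gene. It gave counts of calls and no values for single genes. In that fit the lower Trbv14 call in cluster 7 of the URI library was lost. Without 1 WT library 0 of 36 fold changes of called genes changed sign and 14 moved by over 1.5 times. Counts of changed genes moved beyond 1.5 times in 71 and not in 256, and cells kept before doublet removal ranged over libraries from 6722 (limit of 1000 UMIs) to 9547 (300 UMIs).

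For GS against WT the 3 calls over classes became 8 without a filter on low counts, 0 by DESeq2, 5 at 1000 UMIs, 1 with doublets kept and 10 with equal cells. B cells had 2 without a filter and 1 with equal cells, and monocytes 2 at 1000 UMIs, each from 0. For URI against WT the 7 calls became 12 without a filter, 18 by DESeq2, 28 with a limit per library, 13 with doublets kept and 12 with equal cells. CD4 T cells had 2 at Leiden resolution 2.0 and 3 with equal cells, and B cells 5 without a filter, each from 0. The CD8 T cell call was 0 by DESeq2, 0 at 1000 UMIs, 0 with a limit per library, 0 with doublets kept, 0 at Leiden resolution 2.0 and 0 with equal cells, and monocytes had 0 without a filter. Neutrophils, with 0 calls, had 22 with a limit per library (21 higher, 1 lower) and 7 with doublets kept. In all kept cells the 5 URI calls became 13 without a filter, 2 with DESeq2 size factors, 2 at 1000 UMIs and 1 with a limit per library. For URI against GS the 1 call became 8 without a filter, 16 by DESeq2, 4 with a limit per library, 3 with doublets kept, 2 at Leiden resolution 2.0 and 4 with equal cells, and without a filter B cells had 5 and CD8 T cells 1. List calls fell from 43, 48 and 51 to 0 with an estimated correlation and 0 by fry in each contrast. Both tests rest on 1 residual degree of freedom and their power was not simulated. Their 0 calls therefore neither uphold nor refute the calls at the preset correlation.

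With GS set against WT replicate 1 and URI against WT replicate 2, the correlations of the knockouts' changes were -0.235 in CD4 T cells, -0.343 in B cells, -0.318 in CD8 T cells and 0.0497 in monocytes. The reverse gave -0.480, -0.541, -0.624 and -0.0784. Where both knockouts lie between the WT libraries, such pairings give changes of opposite sign. In CD8 T cells 56.7% (GS) and 62.6% (URI) of all genes compared lay between, and in monocytes 41.9% and 44.5%. The negative values therefore do not show opposite effects of the knockouts, and other causes were not tested. With the gene-wise spread of the real fits, simulated 2-fold changes were recovered in at most 8.96%, and with 1 common spread in 11.6% (URI monocytes). Depth was not varied in the simulations. At the depth found, 0 UMIs of Cpne4 in the URI library allow only a lower bound of 139-fold.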

Other observations

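Some unnamed clusters held states and transcripts not described above. Cluster 8 (158 cells) was led by the interferon-induced Ifit3, Ifit1 and Isg15. Cluster 19 (115 cells, median 13780 UMIs) was led by the proliferation genes Mki67 and Top2a. Cluster 21 (637 cells, median 745 UMIs), led by the hepatocyte transcripts Alb, Apoa2 and Apoa1, held 0.0805% of the GS library, 1.70% of the URI library and 0.125% and 6.75% of the WT libraries. Its share was not tested.

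The granule gene cells of the URI library carried G2M transcripts at 259 CPM, against 28.1 in its other neutrophils. The same levels were 201 and 33.2 CPM in WT replicate 1, 29.9 and 25.8 in WT replicate 2 and 0 and 24.9 in the GS library, which held 23 such cells. Their Y-linked level was 236 CPM (exact 95% interval 216 to 256), below the 310 CPM (288 to 334) of the other neutrophils of that library. In WT replicate 2 it was above, at 145 CPM (96.9 to 208) against 78.4 (68.5 to 89.2), and in the GS library 138 (84.5 to 214) against 96.7 (85.1 to 110). Of the 327 URI cells, 135 belonged to the neutrophil class, 19.97% of it, and 160 were in unnamed clusters. Hspa1a lay over 2-fold below both WT libraries in URI NKT cells, by log2 -2.18 and -2.02, and Hspa1b in URI B cells, by -1.31 and -2.07. Il10 in GS regulatory T cells, most of which lost that name at Leiden resolution 2.0, lay above both, by log2 2.76 and 2.43. These values compare single libraries and have no test.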
